A study of Mus musculus with 6 samples.

How the data were processed

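Expression was measured on a 1-colour Affymetrix array in 6 mouse prostates, 3 from wild-type and 3 from Gli1-/- mice. Per the labels, each sample was the ventral and dorsolateral lobes of 1 mouse. RNA was isolated with a Qiagen RNeasy Plus Mini column, converted to single-stranded DNA targets with the Ambion WT Expression kit, fragmented, labelled with biotin and hybridised, per the labels' protocols. The array model, the probe-set definition, the genome build and the strain of the mice are not given in the sources used here.

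The values were deposited as log2 intensities, 1 column per mouse, and were used as deposited. RMA and Partek are named in the submitters' processing notes, without role, order or version. RMA corrects background, normalizes between arrays and summarises the probes of a probe set on a log2 scale, so fold changes of genes near the array's background are compressed. Sample medians lay between 6.76 and 6.95, and the value distributions of the 6 columns were not identical. The deposited table held 32025 probe sets with no missing values, each named by a RefSeq transcript. Symbols came from a RefSeq gene table for the mouse assembly GRCm38.p6, used here only for names and for which genes neighbour each other. Through it, 25343 probe sets (79.1%) matched 1 gene, 0 matched several and 6682 matched none. Of the unmatched probe sets, 6073 were predicted transcripts and 609 were curated ones. The matched probe sets represented 20263 genes, of which 16974 had 1 probe set and 3289 had several. A gene with several was represented by its brightest probe set over all 6 samples. Values identical to those of another probe set were found for 5726 probe sets.

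The comparison was Gli1-/- minus wild type, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 6 samples, two-sided, with no covariate and no filter on dim probe sets. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Gene lists were tested with limma's camera, which compares a list's genes with all other genes, at a preset correlation of 0.01 between genes. Adjustment was over the 37 lists, and the test was repeated with the correlation estimated for each list. The estimated correlation has the adjusted p that is given beside each call. Limma's fry, in its directional and its mixed form, was run beside camera. For each list the number of genes that passed when adjusted over the list alone is given beside the number over all genes. A list score is the mean, over the list's genes, of log2 values centred on each gene's mean over the 6 mice. The lists held 942 written genes, of which 907 were measured, 12 through an older symbol. Lists covered Hedgehog signalling, the HGF and MET axis, branching growth factors, androgen receptor targets, cell types of the prostate and of adjacent tissue, and general cell programmes. Errors are SDs over 3 mice for group means and SEs from the moderated fit for log2 changes.

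The tests, the lists and the rule for named genes were fixed before the data were examined. Under that rule the text names Gli1, 9 genes of the Hedgehog and HGF pathways whatever their values, and up to 10 rising and 10 falling genes. Predicted gene models and similar unnamed loci were left out of the last group. Where fewer than 10 passed, genes with the smallest unadjusted p and no overlap between the groups filled the places and are given as values only. In each called list 4 genes with the smallest unadjusted p in the list's direction are eligible, and in every other list up to 2. Some genes that the rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

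The procedure was tested on simulated data made from the 20263 genes of this comparison, with 50 genes changed at each size. It recovered 16% of 1.5-fold, 82% of 2-fold and 100% of 4-fold and 8-fold changes. With 156 genes called there, the adjusted p threshold was easier to pass than with the 4 called in the data. These shares therefore do not carry over to the data. There, log2 changes exceeded 1 in 100 genes and fell below -1 in 47, most of them uncalled. A simulated list shifted by 0.3 on the log2 scale was recovered, and 0 unshifted lists were called. The noise was simulated independently for each gene, so this does not measure how often lists of correlated genes are called without a shift. The median SD between replicates was 0.152 and the median SE of a log2 change was 0.12, and the number of arrays limits this precision. Each sample came from a separate mouse, so the limma p-values of single genes measure the spread between mice handled as in this study. Camera at the preset correlation sets a list's genes against all other genes as nearly independent, so its p-values do not measure that spread.

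Alternatives were the replicate number as a block, an intensity trend with robust variance, array weights, quantile normalization, median centring, a filter on dim probe sets, averaging of probe sets, an adjusted p under 0.10, a minimum change of 1.2-fold, camera on ranks, and each mouse left out in turn. Leaving out 2 libraries together was added after the data had been seen. Genes within 5 Mb of Gli1 were compared with 10000 random sets matched on mean expression. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The probe sets without a gene symbol were not used in the comparison of genes. In a limma fit over all 32025 probe sets, 0 of the unnamed ones passed an adjusted p of 0.05 and 544 had an unadjusted p under 0.05.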

Results

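The samples were regenerating prostates of 10-week-old mice. The mice were castrated at 8 weeks, which makes the gland regress, and received a testosterone pellet 2 weeks later, which makes it regrow. The ventral and dorsolateral lobes were collected after 3 days of testosterone. Whole-lobe RNA from 3 wild-type and 3 Gli1-/- mice was profiled, so each value averages epithelium, stroma, vessels and immune cells. Gli1 encodes a transcription factor that is both an effector and a target of Hedgehog signalling, and the comparison asks which transcripts differ in its absence during androgen-driven regrowth.

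The Gli1 probe set itself lay at 6.42 ± 0.12 (SD, n = 3) in wild type and 6.30 ± 0.04 in the mutants, on the log2 scale. The difference was -0.12 (SE 0.10, limma adjusted p = 0.732), with a 95% interval from -0.35 to 0.11. Single mice read 6.28, 6.48 and 6.51 in wild type and 6.34, 6.27 and 6.29 in the mutants, so the groups overlapped. The level stood at the 37.3 percentile of all genes. Which part of Gli1 the allele removes is not given in the sources used here, and a probe set outside that part checks nothing. The genotype labels therefore have no check from this transcript.

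Transcripts of the Hedgehog pathway showed no call in either direction. The sister factors Gli2 and Gli3 differed by -0.05 (SE 0.14) and 0.03 (SE 0.10), the ligand Shh by 0.05 (SE 0.14) and the transducer Smo by 0.19 (SE 0.12). Smo differed by 0.09 with array weights, 0.115 without mutant 1 and 0.28 without mutant 3. The direction of Gli2, Gli3 and Shh changed when single mice were left out. The receptor gene Ptch1, which is induced by Hedgehog signalling, differed by 0.22 (SE 0.18), and by 0.09 without wild-type mouse 3, 0.11 without mutant 1, 0.35 without wild-type mouse 1, 0.38 without mutant 2 and 0.50 without both of the last. Hhip, a Hedgehog-binding antagonist that is also a pathway target, was lower in all 3 mutants, at 7.15 ± 0.56 against 7.85 ± 0.04 (SD, n = 3; limma adjusted p = 0.4). Without mutant 1 its difference shrank from -0.69 to -0.38. Scube2, which aids ligand release, differed by -0.35 (SE 0.14). Of the 17 measured ligand, receptor and Gli factor genes, 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.956; 0.978 with an estimated correlation). That list had a mean of -0.03, a median of 0.03 and an upward test statistic. Among the 20 Hedgehog-response genes 0 passed as well (mean 0.05, adjusted p = 0.554; 0.773 with an estimated correlation). Sfrp1 (0.58, SE 0.16) and Hsd11b1 (0.70, SE 0.21) had the smallest unadjusted p there.

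Hgf, which encodes the ligand of the receptor tyrosine kinase Met, was higher in all 3 mutants. It read 7.22 ± 0.10 against 6.60 ± 0.11 (SD, n = 3), a 1.54-fold difference with a 95% interval of the log2 change from 0.38 to 0.87. That difference did not pass over all genes (limma adjusted p = 0.116) and did pass adjusted over the list alone, where it was the 1 gene of 16 to rise. Array weights brought the Hgf log2 change to 0.52 and its adjusted p to 0.00961, in a fit that rests mainly on 2 mice. Hgf stayed uncalled in every other alternative. Its limma adjusted p was 0.104 with the block, 0.186 with quantile normalization and 0.787 with a minimum change of 1.2-fold. With each mouse left out it was 0.111 to 0.351. Met differed by 0.14 (SE 0.14), and by 0.04 without mutant 1, 0.07 with array weights, 0.20 without wild-type mouse 1 and 0.27 without mutant 3. The list of the HGF and MET axis was higher in the mutants by a mean of 0.16, with 13 of 16 genes positive (camera adjusted p = 0.00267; adjusted p = 0.352 with an estimated correlation). Of the 16, 6 are microRNA-26 genes and the phosphatase genes that host them, of which 4 were positive (mean -0.06). Of the other 10, 9 were positive (mean 0.28). Further members were Spint1 (0.43, SE 0.14), an inhibitor of the HGF activator, the protease gene Hpn (0.40, SE 0.15) and Plat (0.46, SE 0.18), which encodes tissue plasminogen activator. The 29 branching growth factors were not called (mean -0.01, adjusted p = 0.956; 0.978 with an estimated correlation), and their median of -0.02 opposed an upward statistic. Within that list Egf (-0.75, SE 0.17) and Bmp7 (-0.48, SE 0.12) were lower in all 3 mutants.

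Of 20263 genes, 4 changed, 2 upward and 2 downward (limma adjusted p under 0.05). Ms4a5, a member of the membrane-spanning 4-domain family, rose from 4.16 ± 0.30 to 10.23 ± 0.88 (SD, n = 3), a 67.2-fold difference between the deposited values (adjusted p = 0.00303). Sectm1b, which encodes a secreted and transmembrane protein, rose 3.64-fold, from 6.64 ± 0.21 to 8.50 ± 0.32 (adjusted p = 0.0385). Spink11, a Kazal-type serine protease inhibitor gene, was 8.72-fold lower in the mutants, at 4.63 ± 0.14 against 7.76 ± 0.33 (adjusted p = 0.00121). Hal, which encodes the histidine-degrading enzyme histidine ammonia-lyase, was 5.43-fold lower, at 5.74 ± 0.01 against 8.18 ± 0.05 (adjusted p = 9.99e-05). The wild-type level of Ms4a5 and the mutant level of Spink11 stood at the 9.6 and 14.7 percentiles of all genes in those groups, a range where fold changes on arrays are compressed. Hal and Spink11 kept their calls with every single mouse left out. The adjusted p of Ms4a5 was 0.0597 without wild-type mouse 3, and Sectm1b passed only when mutant 2 was the mouse left out, with an adjusted p up to 0.183 otherwise.

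**Figure D1:**
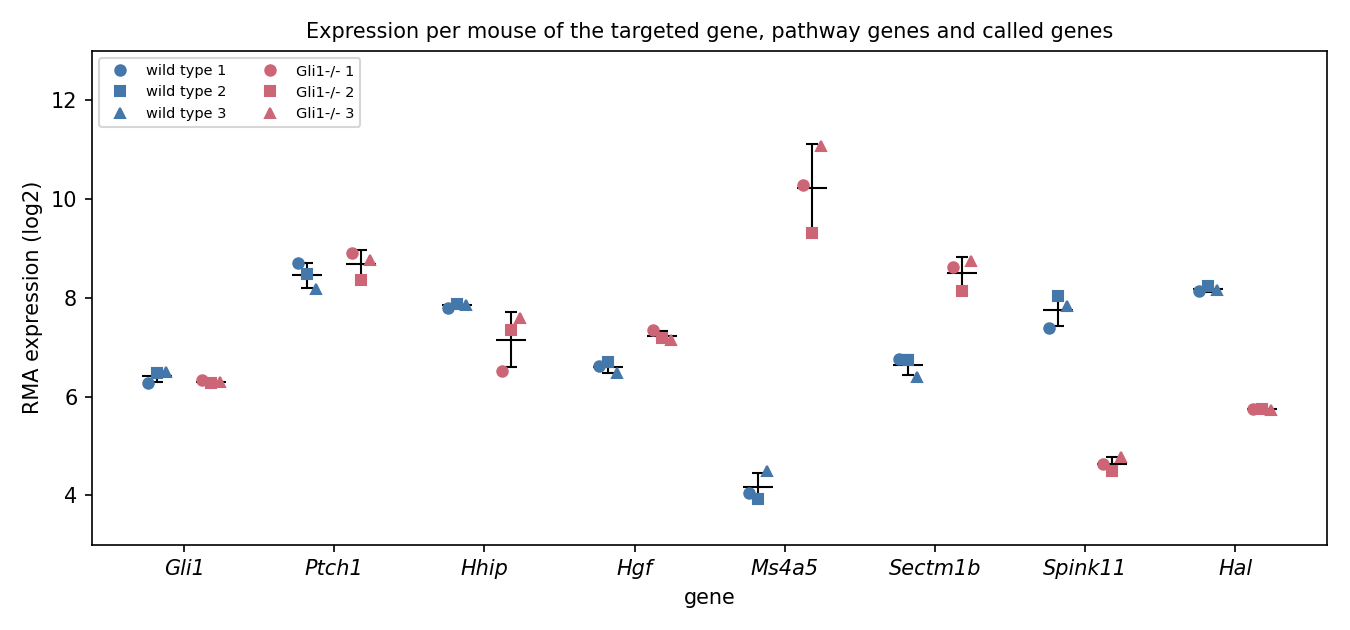
Log2 RMA expression of 8 genes in each mouse (y axis), by gene (x axis). Points are single mice, blue for wild type and red for Gli1-/-, with the shape giving the mouse number. Horizontal bars and whiskers are means and SDs of 3 mice. Gli1 and Ptch1 overlap between the groups, while Ms4a5 lies between 9.32 and 11.08 in the mutants and at or below 4.50 in wild type.

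With the called genes included, 30 genes had an adjusted p under 0.10, 18 higher and 12 lower in the mutants. An unadjusted p under 0.05 was found for 2129 genes (10.5%), 1201 higher and 928 lower. In 2907 genes (14.3%) the groups did not overlap, against 10% by chance. Log2 changes exceeded 1 in 100 genes and fell below -1 in 47. Several genes with an adjusted p from 0.0626 to 0.0882 were higher in all 3 mutants. The acute-phase protease inhibitor gene Serpina3n differed by 2.78 (SE 0.37) and its relatives Serpina3c and Serpina3h by 0.99 and 1.16, although probes can be shared within this family. The galectin gene Lgals4 differed by 1.90 (SE 0.21), Lipo3 by 2.14 and Vtcn1, an immune checkpoint ligand gene, by 1.54. Differences of 0.93 and 0.67 were measured for the secretoglobin gene Scgb3a1 and for Pcolce, an enhancer of procollagen processing. Lower in all 3 mutants were the defensin gene Defb10 (-1.94), Aadacl4fm4 (-1.21), the complement protease gene C1rb (-1.14), the anion exchanger gene Slc26a3 (-1.14) and the fucosyltransferase gene Fut9 (-1.12). The basement membrane collagen gene Col4a6 (-1.04), Azgp1 (-0.82) and the activin receptor gene Acvr1c (-0.78) were lower as well.

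Of the 37 gene lists, 23 were called with the preset correlation, 13 higher and 10 lower in the mutants. With correlations estimated from these 6 samples 0 were called by camera (lowest adjusted p = 0.18, 3 lists at an unadjusted p under 0.05). Directional fry called 0 as well (lowest adjusted p = 0.14, 10 at an unadjusted p under 0.05). Mixed fry, which counts changes in either direction, called 12. Among them were the androgen receptor target, adipocyte and Wnt target lists, which camera did not call (mixed fry adjusted p = 0.00318, 0.00318 and 0.00508). In 14 of the 23 called lists the scores of the 2 groups did not overlap. Those lists were called for a difference between the same groups, so this count is not separate support. Array weights ended the calls of the lymphocyte, seminal vesicle, skeletal muscle, cholesterol and glutathione lists, lowered the macrophage mean from 0.57 to 0.23, and took the secretory, oxidative phosphorylation and ribosomal means to -0.38, -0.38 and -0.44. Without wild-type mouse 1 and mutant 2 the last 3 means were -0.41, -0.46 and -0.51, the seminal vesicle mean was -0.91, and the lymphocyte and cholesterol calls were lost. Leaving out dim probe sets moved the urothelial mean to 0.58 and the secretory mean to -0.13.

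Genes of macrophages and other myeloid cells were higher in the mutants by a mean of 0.57 on the log2 scale, with 29 of 31 positive. Adjusted over the list alone 15 of them rose, and 0 passed over all genes. Msr1, a scavenger receptor gene, read 7.24 ± 0.24 against 6.15 ± 0.24 (SD, n = 3), and Laptm5, C1qc and the macrophage marker Adgre1 differed by 0.88, 0.68 and 0.75. The list's camera adjusted p was 1.35e-15, and the adjusted p was 0.352 with an estimated correlation. Chemokine, cytokine and complement genes were higher by a mean of 0.66, and 12 of 36 rose and 1 fell adjusted over the list alone (adjusted p = 9.32e-12; adjusted p = 0.18 with an estimated correlation). The siderophore-binding lipocalin gene Lcn2 read 12.58 ± 0.78 against 10.21 ± 0.35 (SD, n = 3), and the complement genes C3 and Cfb and the cytokine gene Il1a differed by 0.70, 1.08 and 0.50. Interferon-response genes differed by a mean of 0.40 with 33 of 39 positive and 0 passing adjusted over the list alone (adjusted p = 1.13e-09; adjusted p = 0.38 with an estimated correlation). Examples were Stat2 (0.62), the chemokine gene Cxcl9 (0.60) and Parp14 (0.51). Scores of the interferon list overlapped between the groups. They were -0.105, -0.121 and -0.371 in wild-type mice 1 to 3 and -0.15, 0.219 and 0.528 in mutants 1 to 3. Lymphocyte genes differed by a mean of 0.14, with 2 of 27 rising and 1 falling adjusted over the list alone (adjusted p = 0.012; adjusted p = 0.42 with an estimated correlation). Ptprc (0.68), Cd3g (0.78), Gzmb (0.74) and Ms4a1 (0.44) were higher in all 3 mutants. The lymphocyte call was lost without wild-type mouse 1 (mean 0.09), and the interferon mean was 0.23 without mutant 3. Leaving out wild-type mouse 1 and mutant 2 together lowered the macrophage mean to 0.28, the chemokine mean to 0.41 and the lymphocyte mean to 0.06. Skeletal muscle genes ran with the macrophage genes: their scores were -0.65, 0.07 and -0.42 in wild-type mice 1 to 3 and 0.85, 0.31 and -0.16 in mutants 1 to 3.

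**Figure D2:**
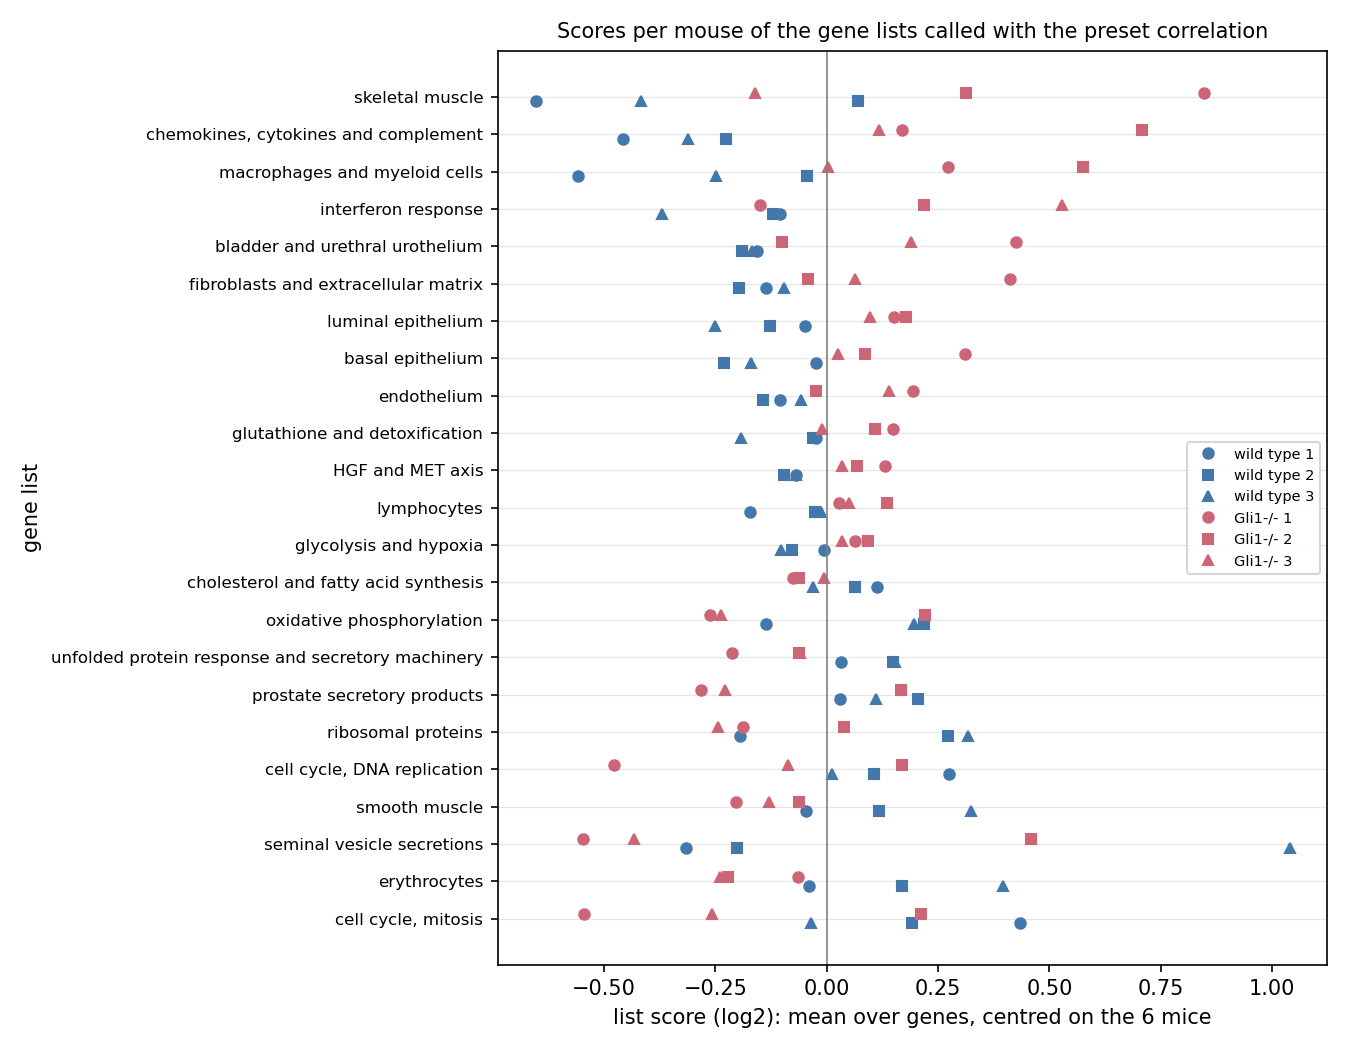
Scores of the 23 gene lists called with the preset correlation (y axis) in each mouse. The score (x axis, log2) is the mean over the list's genes, centred on the 6 mice; blue is wild type, red is Gli1-/-, and the shape gives the mouse number. Macrophage scores of the mutants lie between 0.00 and 0.58 and those of wild type between -0.56 and -0.05, whereas seminal vesicle scores are highest in wild-type mouse 3 (1.04) and mutant 2 (0.46).

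Epithelial markers were also higher in the mutants, while secretory transcripts were lower on average. The urothelial list, which shares Krt7 with the luminal list, rose with them (mean 0.34, adjusted p = 0.00353; adjusted p = 0.409 with an estimated correlation). Of 35 luminal genes 27 were positive (mean 0.29), and 9 rose and 1 fell adjusted over the list alone (adjusted p = 3.99e-05; adjusted p = 0.352 with an estimated correlation). The mucin gene Muc1 differed by 0.80 (SE 0.11), and Psca and Ly6a, surface markers of progenitor-like or proximal epithelial cells, by 1.52 and 0.92. All 22 basal genes were positive (mean 0.28), with 0 passing adjusted over the list alone (adjusted p = 9.85e-07; adjusted p = 0.352 with an estimated correlation). Among them were the basal master regulator Trp63 (0.49, SE 0.16), Bcl2 (0.46) and Snai2 (0.24). Prostate secretory products were lower, with a mean of -0.23, but their scores overlapped between the groups. These scores were 0.029, 0.204 and 0.11 in wild-type mice 1 to 3 and -0.283, 0.167 and -0.228 in mutants 1 to 3. Over all genes 1 of 27, Spink11, fell, and adjusted over the list alone 11 fell and 3 rose (adjusted p = 0.000221; adjusted p = 0.356 with an estimated correlation). Tgm4, a transglutaminase gene of the secretory epithelium, read 12.96 ± 0.05 against 13.48 ± 0.10 (SD, n = 3), Azgp1 differed by -0.82 and Fgl1 by -1.87. The secretory mean was -0.15 without mutant 1 and -0.37 without mutant 2, and seminal vesicle scores stood at 1.04 in wild-type mouse 3 and 0.46 in mutant 2 against -0.20 or lower in the other 4. Camera did not call androgen receptor targets (25 genes, adjusted p = 0.722, or 0.803 with an estimated correlation). Their mean of 0.02 and median of 0.01 opposed its downward statistic. Mixed fry did call them (adjusted p = 0.00318). Adjusted over the list alone 2 of them rose and 5 fell, with Psca higher and the androgen-dependent secretory gene Pbsn (-0.88, SE 0.21) lower in all 3 mutants.

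Stromal lists moved apart. Fibroblast and matrix genes were higher by a mean of 0.29, with 31 of 38 positive and 2 rising adjusted over the list alone (adjusted p = 4.9e-08; adjusted p = 0.38 with an estimated correlation). The collagen cross-linking enzyme genes Lox and Loxl1 differed by 0.81 and 0.55, Fbln1 by 0.60 and C3, which the chemokine and complement list also holds, by 0.70. Smooth muscle genes were lower, with a mean of -0.26 and 5 of 31 falling adjusted over the list alone (adjusted p = 3.75e-06; adjusted p = 0.409 with an estimated correlation). The smooth muscle myosin gene Myh11 read 9.63 ± 0.11 against 10.43 ± 0.30 (SD, n = 3), and Synpo2, Pcp4 and the myosin light chain kinase gene Mylk differed by -0.76, -0.83 and -0.70. Endothelial genes were higher by a mean of 0.21, with 23 of 24 positive and 1 rising adjusted over the list alone (adjusted p = 1.4e-05; adjusted p = 0.352 with an estimated correlation). The lymphatic markers Lyve1 (0.58) and Pdpn (0.44) and the vascular markers Emcn (0.43) and Plvap (0.36) led it. The fibroblast mean was 0.15 without mutant 1, and the smooth muscle mean was -0.17 without wild-type mouse 3. Fibroblast scores were -0.137, -0.196 and -0.097 in wild-type mice 1 to 3 and 0.411, -0.043 and 0.063 in mutants 1 to 3. Mutant 1 also had the highest scores of the urothelial (0.425) and skeletal muscle (0.848) lists.

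Proliferation genes were lower on average in the mutants. Mutants 1 and 3 scored below all wild-type mice, while mutant 2 lay within the wild-type range for both lists. All 34 mitosis genes were negative (mean -0.39, adjusted p = 1.07e-09; adjusted p = 0.42 with an estimated correlation), with 0 passing adjusted over the list alone. The cytokinesis gene Anln differed by -0.80 (SE 0.19), and Cenpf, Hmmr and the mitotic kinase gene Aurka by -0.47, -0.70 and -0.65. Of 37 DNA replication genes 36 were negative (mean -0.26, adjusted p = 6.43e-06; adjusted p = 0.541 with an estimated correlation), again with 0 passing adjusted over the list alone. Ccne2 (-1.02), Prim1 (-0.64), Rrm2 (-0.56) and E2f1 (-0.32) were examples. Mitosis scores were 0.43, 0.19 and -0.04 in wild-type mice 1 to 3 and -0.54, 0.21 and -0.26 in mutants 1 to 3. The mitosis mean was -0.22 without mutant 1 and -0.60 without mutant 2; the replication mean was -0.09 and -0.41 there, and its call was lost without wild-type mouse 1 (adjusted p = 0.134).

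Genes of the unfolded protein response and the secretory machinery were lower in the mutants, 29 of 30 negative with a mean of -0.22 (adjusted p = 2.65e-08; adjusted p = 0.352 with an estimated correlation). No gene of the list passed adjusted over the list alone. The stress-induced factor gene Ddit3 differed by -0.55, and Pdia6, Edem1 and Herpud1, which act in folding and clearance of proteins in the endoplasmic reticulum, by -0.33, -0.30 and -0.38. Ribosomal protein genes had a mean of -0.26 (20 of 23 negative, adjusted p = 0.000105; adjusted p = 0.471 with an estimated correlation), with Rpl34 (-0.68), Rps19 (-0.51), Rpl8 (-0.35) and Rpl22 (-0.22) as examples. Oxidative phosphorylation genes had a mean of -0.19 (23 of 30 negative, adjusted p = 0.0124; adjusted p = 0.772 with an estimated correlation), led by Ndufa1 (-0.71), Cox7b (-0.45), Atp5o (-0.44) and Cox4i1 (-0.48). Adjusted over the list alone 0 genes of either list passed. Oxidative phosphorylation scores were 0.22, 0.20 and 0.22 in wild-type mice 2 and 3 and mutant 2, against -0.14, -0.26 and -0.24 in wild-type mouse 1 and mutants 1 and 3. Ribosomal scores in the same order of mice were 0.27, 0.32 and 0.04, against -0.19, -0.19 and -0.24. The oxidative phosphorylation call was lost without wild-type mouse 2 (mean -0.12), mutant 1 (-0.10) or mutant 3 (-0.11), and the mean was -0.30 without wild-type mouse 1 and -0.34 without mutant 2. The ribosomal mean was -0.43 without wild-type mouse 1 and -0.17 without wild-type mouse 3.

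Metabolic lists moved by smaller amounts. Glycolysis and hypoxia genes were higher by a mean of 0.13 (18 of 25 positive, adjusted p = 0.0105; adjusted p = 0.352 with an estimated correlation), among them Eno1 (0.68), Aldoa (0.37), Pfkp (0.26) and the glucose transporter gene Slc2a1 (0.40). Glutathione and detoxification genes were higher by 0.17 (18 of 25 positive, adjusted p = 0.0094; adjusted p = 0.352 with an estimated correlation), with Cyp2f2 (0.76), the haem oxygenase gene Hmox1 (0.42), Ephx1 (0.54) and Ces1d (0.37) as examples. In both lists 0 genes passed adjusted over the list alone. Cholesterol and fatty acid synthesis genes had a mean of -0.10, with 3 of 29 falling adjusted over the list alone (adjusted p = 0.012; adjusted p = 0.38 with an estimated correlation). Mvd (-0.41), Stard4 (-0.51), Insig1 (-0.55) and Fdps (-0.33) were lower. Without wild-type mouse 3 the calls of the glycolysis (mean 0.11) and glutathione (0.11) lists were lost, and the cholesterol call was lost without wild-type mouse 1 (-0.07) or mutant 2 (-0.09).

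Markers of tissue that lies beside the prostate or is carried by blood also differed. Skeletal muscle genes were higher in the mutants by a mean of 0.67, with 25 of 26 positive and 0 passing adjusted over the list alone (adjusted p = 8.61e-09; adjusted p = 0.409 with an estimated correlation). The myosin light chain gene Myl1 read 8.48 ± 0.83 against 6.15 ± 1.25 (SD, n = 3), and Neb, Myh4 and Actn3 differed by 1.29, 1.18 and 0.35. Of the urothelial genes given above 10 of 14 were positive, with Gsdmc2 (1.87), a gene with close copies, Krt7 (0.71), Sprr1a (1.03) and Gsdmc4 (0.37). Seminal vesicle genes had a mean of -0.35, and 1 of 13, Svs3a (-1.38, SE 0.22), fell adjusted over the list alone (adjusted p = 0.0188; adjusted p = 0.42 with an estimated correlation). Erythrocyte genes had a mean of -0.35, and 1 of 8 fell adjusted over the list alone (adjusted p = 0.00157; adjusted p = 0.352 with an estimated correlation). The haem synthesis genes Alas2 (-0.65) and Fech (-0.22) were lower in all 3 mutants. The seminal vesicle mean was 0.09 without wild-type mouse 3, which reversed it, and between -0.66 and -0.16 with any other mouse left out. The skeletal muscle mean was 0.41 without mutant 1, and the urothelial mean was 0.22 without mutant 1.

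The remaining lists were not called by camera, while mixed fry called the Wnt target and adipocyte lists. Genes of the TGF-beta and BMP pathways had a mean of 0.15 (28 genes, adjusted p = 0.0561; 0.445 with an estimated correlation), with Tgfbi at 0.58 and Id4 at -0.51. Neuroendocrine and neuronal genes had an adjusted p of 0.164 (0.773 with an estimated correlation), with Stmn2 at 0.38, and immediate early and heat shock genes one of 0.314 (0.773), with Ier3 at 0.70 and Hsph1 at -0.58. The Notch pathway (adjusted p = 0.416; 0.757 with an estimated correlation) held Hey1 at -0.50. Among 20 Wnt targets (adjusted p = 0.479; 0.762 with an estimated correlation) 2 rose and 1 fell adjusted over the list alone, with Apcdd1 at -0.47 and Dkk3 at 0.82. The adipocyte list (adjusted p = 0.499; 0.815 with an estimated correlation) contained the adipogenic receptor gene Pparg, at 8.31 ± 0.20 against 7.22 ± 0.25 (SD, n = 3), and Acvr1c. Adjusted over that list alone 1 rose and 1 fell. For vas deferens and epididymis genes (adjusted p = 0.554; 0.815 with an estimated correlation) the mean of -0.15 opposed a median of 0.00, with Adam7 at -1.89. Mast cell genes (adjusted p = 0.585; 0.889 with an estimated correlation), Schwann cell and glial genes (0.827; 0.921) and mesothelial genes (0.956; 0.978) had means of -0.08, 0.03 and -0.01. The Schwann cell mean opposed a median of -0.04, and Mbp differed by 0.41 in its brightest probe set and by -0.07 to -0.04 in its others.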

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

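Gli1 kept its direction and stayed uncalled in every alternative that gave a value (-0.19 to -0.08); Gli1 and Spink11 lie below the dim filter, which gives them no value. Genes near Gli1 kept a median between -0.04 and -0.01. The 2 genes called higher became 16 with the replicate block, 1948 with array weights, 1 with quantile normalization, 4 with median centring, 18 at an adjusted p under 0.10, 1 with a minimum change of 1.2-fold and 0 to 12 with each mouse left out. The 2 called lower became 9 with the replicate block, 2732 with array weights, 4 with median centring, 1 with the dim filter, 12 at an adjusted p under 0.10 and 2 to 6 with each mouse left out. Leaving out wild-type mouse 1 and mutant 2, chosen after seeing the data as the ends of the second principal component, gave 167 higher and 701 lower. It leaves wild-type mice 2 and 3 against mutants 1 and 3, which a split that differs from the genotype only in the mice left out also separates. Array weights, whose estimation did not converge, gave wild-type mouse 2 a weight of 7.22, mutant 3 one of 2.26 and the others 0.353 to 0.899, so by construction those fits rest mainly on 2 mice. All 4 called genes were among those called with the block, the weights, the centring and the pair left out. Sectm1b lost its call in some settings, with an adjusted p of 0.0814 with quantile normalization, 0.065 with a minimum change and 0.00128 to 0.183 over all alternatives. For the counts moved by the block, centring and quantile normalization the cause was not tested. Of the lists, 0 were called with estimated correlations, and 19 to 25 in every other setting. The drop to 0 comes with how camera's correlation is set, since nothing else was changed. In place of 0.01, estimates were 0.805 for mitosis, 0.539 for macrophage and -0.001 for glycolysis genes. For the spread over the other settings the cause was not tested.

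Whether the numbers 1 to 3 pair the mice cannot be told from the values. Deviations from the group mean correlated at 0.162, 0.248 and -0.153 between same-numbered mice. Across the groups, wild-type mouse 1 correlated best with mutant 3 (0.249), and mutant 2 with wild-type mouse 2 (0.248). These few correlations, of deviations that depend on each other within a group, cannot decide it. With the replicate number as a block the calls went from 4 to 25.

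Directions reversed for Gli2 (0.06 with array weights; -0.127 to 0.072 with each mouse left out), Gli3 (-0.017 to 0.077) and Shh (-0.082 to 0.133), for 9530003J23Rik (0.16 with array weights) and for the seminal vesicle list (-0.663 to 0.086), whose sign rests on wild-type mouse 3. Shh kept the direction of the main fit (0.048) with array weights (0.298) and without wild-type mouse 1 and mutant 2 (0.192). For the genes the cause was not tested. Over the named genes and settings, 1893 values kept direction and side of the threshold, 191 gained a call, 8 lost one and 7 reversed. Over the called lists 326 kept both, 39 lost the call and 1 reversed. Genes near background have compressed changes, and changes of 1.5-fold were mostly missed on simulated data (16% recovered).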

Other observations

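The tests below on the number of called genes in other splits, on a single mutant mouse, on the luminal share, on skeletal muscle, on sequence linked to Gli1 and on unlinked variants were chosen after the results they bear on had been seen. All genes named in this part were chosen after their values were seen, unless named before. Serum amyloid genes, part of the acute-phase response, were high in 1 mouse. In mutant 2 Saa3 read 13.05, Saa1 10.53 and Saa4 9.78, against at most 8.71, 4.29 and 6.59 in the other 5 mice. Mmp12 and Spp1, both expressed by activated macrophages, were highest in mutant 1, at 10.27 and 11.30, against at most 7.38 and 9.01 elsewhere. Ibsp, a bone matrix gene, read 8.72, 9.60 and 7.90 in wild-type mice 1 to 3 and 4.97, 4.77 and 10.21 in mutants 1 to 3. Of these 6 genes 0 had a limma adjusted p under 0.05.

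BC018473 read 12.22 and 12.18 in wild-type mice 1 and 2 but 4.66 in wild-type mouse 3, and 4.25, 4.28 and 4.57 in mutants 1 to 3. Svs5 and Pate4, secretory genes of the seminal vesicle, read 10.36 and 8.73 in wild-type mouse 3 and 9.37 and 10.71 in mutant 2, against at most 6.07 and 5.57 in the other 4 mice. Of the 13 seminal vesicle genes measured, 4 were higher in both of these mice than in each of the other 4. The further pair was Svs2 (8.115 and 6.833, against at most 5.347) and Svs4 (6.895 and 6.507, against at most 5.552). The other 9 did not share this pattern, and 9530003J23Rik was highest in wild-type mice 1 and 3, at 10.21 and 10.69. Sectm1a, a relative and neighbour of the called gene Sectm1b, was higher in the mutants by 1.38 (SE 0.24, limma adjusted p = 0.125).

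The mice also differed by a grouping that follows the genotype in part, with wild-type mouse 1 and mutant 2 exchanged. The first principal component (42% of the variance) read -2.55, 19.98 and 31.4 in wild-type mice 1 to 3. It read -26.48, -3.72 and -18.64 in mutants 1 to 3. Every wild-type mouse thus lay above every mutant, with wild-type mouse 1 and mutant 2 nearly level. This component therefore does not show the exchange, which was seen in a split of the mice. Setting wild-type mice 2 and 3 and mutant 2 against the other 3 called 500 genes, against 4 for the real groups, which points to a structure of the samples. Dim or bright genes moving as a block are argued against, since the change of that split correlated with mean expression at a Spearman rho of -0.076 across genes, which are not independent replicates. Between-array scaling stays open, since 208 genes were still called after quantile normalization, as does a trend with gene length, where the rho with genomic length was 0.216 and longer genes were higher in wild-type mouse 1 and mutants 1 and 3. The labels give no batch, so no biological explanation and no handling date was tested.

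The 6 mice allow 10 splits into groups of 3, too few for a share under 0.05. For the 4 called genes, 2 of the splits gave as many, with 500 as the highest of the others. For the 23 called lists, 1 split gave as many, the real one, with 16 as the highest and 6 as the lowest of the others.

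Macrophage, chemokine and complement genes were higher in the mutants, and no biological explanation was tested. One mutant carrying the macrophage difference is argued against. The macrophage mean stayed at 0.422 or above with any mutant left out, and the list's camera call at the preset correlation held. All 6 mice do not give that call when camera estimates the correlation (adjusted p = 0.352). This test did not cover the chemokine and complement list, which holds Saa1 and Saa3, both high in mutant 2 alone. Its mean was lowest without mutant 2, at 0.474. A lower share of luminal epithelium would raise every other cell type alike. The smooth muscle median of -0.325 (SE 0.08 over genes, which are not independent replicates) goes the other way. A separate fall of smooth muscle genes would hide such a rise, so the median alone cannot decide. Luminal genes were themselves higher in the mutants (mean 0.285, 27 positive and 8 negative), while secretory products were lower (mean -0.229). Skeletal muscle taken along with the gland stays open. The macrophage and muscle lists were both called higher in the mutants, so their scores share a group difference. The exact permutation p-values disregard the groups and do not set that difference apart. Macrophage and muscle scores correlated over the 6 mice at a Spearman rho of 0.886 (exact p = 0.0333) and a Pearson r of 0.823 (exact p = 0.05). Without the 2 mice farthest from the median muscle score these were 0.8 and 0.886; this 1 relation was computed, 0 of the muscle genes are in another list, and the brightest, Acta1 and Eno3, read 9.74, 10.20 and 10.26 and 8.04, 8.83 and 7.85 in wild type and 10.56, 10.32 and 9.81 and 9.77, 9.22 and 8.38 in the mutants.

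The differences in Ms4a5, Hal and Spink11 are large and nearly of the on and off kind, so sequence from another strain is a candidate explanation. Sequence linked to the targeted Gli1 allele is argued against for the 4 called genes as a set by their positions: 3 of them lie on other chromosomes than Gli1, and 1, Hal, lies with it on chromosome 10. The 157 genes within 5 Mb of Gli1 had a mean absolute log2 change at the 30.7 percentile of matched random sets, with 0 called by limma and 13 at an unadjusted p under 0.05. Their median was -0.02 (permutation p = 0.742). For Hal alone a linked segment stays open, since the 165 genes between Hal and Gli1 stood at the 34.3 percentile, and a segment with few regulatory variants would also give both percentiles. Unlinked variants cannot be told apart from an effect of the genotype, because the strains are not given in the sources used here; 9 genes differed by over 4 log2 units between mice of 1 group, BC018473 among them, and a loss of Gli1 acting on these genes stays open as untested.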
